A study of Mus musculus with 3057 samples.

How the data were processed

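The series profiled H3K27ac, a histone mark of active promoters and enhancers, in single cells of C57BL/6 mouse organs with CoBATCH. In this assay an antibody guides a fusion of Protein A and the transposase Tn5 to marked chromatin, where Tn5 inserts indexed adapters. Per the labels, organs were digested with collagenase II and trypsin, cells were fixed with formaldehyde, and each cell is labelled EC, read here as endothelial cell. How the cells were sorted or gated, the age of the mice and their number are not given in the sources used here. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, aligned to mm10 with Bowtie2 2.3.1, and passed through Picard (version not stated) and bedtools 2.25.0. The role of each tool is not given in the sources used here. The deposited file of each cell lists aligned reads, and its numeric column is a score, the mapping quality given by the authors' aligner, which ran from 31 to 44. That score was not used as a measurement.

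Each of the 3057 deposited samples is 1 cell. The labels name no animal, age or replicate, so all cells of an organ were summed and each organ counted as 1 sample. Cells are not replicates, and no p-value, standard error or test between organs was computed. The deposited files held 28565012 reads. Mates on the same chromosome were joined by read name into 14271774 pairs, and 21455 unpaired reads were left out. The few reads that formed neither such a pair nor a single read were also left out. Read names were of 1 form except for 3 reads. Pairs on the mitochondrial genome (3252) and on unplaced sequences (7425) were set aside. The other 14261097 pairs are called fragments and were placed by their midpoint. They include 1479 on the Y chromosome, which enter the totals. Pairs with the same ends within a cell, 7460 in all the deposited pairs, were kept. No cell was removed. The shallowest file held 3050 reads. A cell had a median of 2896 fragments, with a range from 1519 to 101558.

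Genes came from the RefSeq annotation of GRCm38, the assembly also called mm10, with 21887 protein-coding genes. The table used here gives neither strand nor transcripts, so the planned windows around transcription start sites could not be drawn. The window of a gene was therefore its annotated span plus 5 kb on either side, and the level of a gene is its fragments per kb of window per 1000000 fragments of the organ. Windows of neighbouring genes overlap, for example within the Hox clusters and among the C1q genes, and such genes are not independent. The planned search for sequence motifs was not run because no genome sequence was used. Genes for chemosensory receptors, 1515 in number, were taken as inactive and gave the background.

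Each of the 7 organs outside the brain was compared with the other organs pooled. The brain, as the sum of left forebrain, right forebrain and hindbrain, and each of its 3 regions were compared with the 7 other organs. Left was also compared with right forebrain, and forebrain with hindbrain. A ratio is fragments per 1000000 in the organ over the same quantity in the comparison organs, with its exact conditional 95% interval. A gene was called higher when the ratio was at least 1.5 and the interval lay above 1, and lower in the mirrored case. Genes needed 20 fragments observed or expected. This is a rule of size and not a test between organs. All intervals cover counting error only, and PCR copies and differences between animals are outside them.

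There were 31 gene lists. The lists, the comparisons, the rule for naming genes, the cell type markers and the first set of alternative settings were fixed before the data were examined. A list is given by the median over its members, with a 95% interval from 2000 Poisson draws of the fragment counts. Its percentile is its place among 10000 random lists of the same size, matched on window length for levels and on mean level for ratios. Named genes are the 5 with the highest lower bound of the ratio among genes higher in that organ than in every other, with at least 20 fragments. The 2 with the lowest upper bound were also taken. From each list came the 3 members with the highest ratio and the 1 with the lowest in the organ the list is about, or by level over all organs for general lists. A gene named outside this rule is said to be so. Some results that this rule names are not reported here. Distal regions are bins of 1 kb over 5 kb from any gene end, with at least 10 fragments, and the 2 with the highest lower bound per organ were named. Where the comparison had no fragments, the ratio was set against a floor of 3 fragments over the pooled organs. On simulated counts the size rule recovered between 37.5% and 57.5% of genes set at 1.5-fold and between 96.2% and 100% of those at 2-fold. It called between 0.266% and 0.655% of unaltered genes higher. These rates hold for simulated counts only. They are not error rates for the real libraries, where left and right forebrain also differed.

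Single cells were compared on 251498 bins of 5 kb, each found in at least 10 cells. Counts were weighted by term frequency and inverse document frequency and reduced to 30 components by singular value decomposition (SVD). The first component was left out because it followed depth (r = 0.94 across cells with log10 of fragments). Each cell's 15 nearest neighbours by cosine distance were taken, and cells were grouped with the Leiden method at resolution 1. An approximate SVD was run first, which gave clusters that differed between settings of the linear algebra library. An exact SVD replaced it, and the approximate one is kept as an alternative. No doublet caller was run, and the deepest 5% of cells per organ were left out in 1 alternative. A cluster was named from the fixed markers when a list had a median log2 ratio of at least 0.5, at least 3 members higher and no rival class. It was also required that its top 10 genes held no more markers of other classes than of its own, and that inactive genes stayed under 1.5 times their level in all cells. This naming rule was written after the first clusters had been seen, and its condition on inactive genes after the exact clusters had been seen. Class shares by organ come from a second clustering that left out 3894 bins overlapping any listed gene.

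The first set of alternative settings covered the scaling, the weight of each cell, depth, the deepest cells, odd-numbered and even-numbered cells, filters, bin size, components, neighbours, resolution and the weight of the comparison organs. The planned windows around transcription start sites, the gene body with an upstream flank, and scaling within start site windows were not run as written. In their place, windows of 5 kb or 2 kb on either side of the gene end with more fragments, and scaling to fragments within 5 kb of any gene end, were added after seeing the data. Also added then were removal of background, of leukocyte-like cells or of fragments shared between cells, use of endothelial-like cells alone, other clustering seeds and the settings named in the closing part. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.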

Results

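H3K27ac was profiled in 3057 single cells labelled EC from 10 mouse organs, and the design sets organ against organ. The cells came from left forebrain (351 cells), right forebrain (287), hindbrain (305), heart (288), lung (235), liver (389), kidney (433), small intestine (74), limb muscle (480) and skin (215). Summed over cells, the organs held between 383386 fragments (small intestine) and 2604392 (liver). Left forebrain held 1386317 fragments, right forebrain 951897, hindbrain 1126203, heart 1273941, lung 1163672, kidney 2075519, limb muscle 2153945 and skin 1141825. The median per cell ran from 2393 in right forebrain to 4232 in liver. The share of fragments within 5 kb of a gene end lay between 29.7% (exact 95% interval 29.6 to 29.8) in liver and 33.7% (33.6 to 33.8) in hindbrain. Genes taken as inactive, those of chemosensory receptors, had levels from 0.0598 in right forebrain to 0.125 in liver, in fragments per kb per 1000000 fragments. Each organ is 1 sample without replicates. Every interval covers counting error only, and "higher" and "lower" describe these libraries by a rule of size. For a list these words give only the direction of its median, and the rule of size applies to its members.

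The first question was whether the cells carried the mark at endothelial genes, and how much stood at genes of other cell types. Pan-endothelial genes stood above inactive genes in every organ. The median level of 25 pan-endothelial genes lay between 1.07 (0.795 to 1.22) in small intestine and 2.44 (2.09 to 2.68) in heart, at percentiles from 96.4 to 100 among random lists. In each organ this was at least 9.87 times the level of the inactive genes. Lists of other cell types also stood high in some organs. The pan-endothelial list ranked 2 of 31 by median level in heart but 13 in small intestine. There it lay below mural (1.28), cardiomyocyte (1.16) and lung epithelium (1.09) genes. In skin the cardiomyocyte list (1.45) was above it (1.30). A level above inactive genes therefore does not by itself name the cell type. Over all organs, Egfl7, which encodes a secreted protein of endothelial cells, had the highest level of the pan-endothelial list at 8.48. Rasip1, a regulator of vessel lumen formation, followed at 5.88 and Eng, a co-receptor for TGF-beta, at 4.01. Emcn was the lowest at 0.135.

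By median level per kb of gene window, leukocyte genes stood above pan-endothelial genes in most organs. Among random lists matched on window length, both lists ranked near the top there. Pan-endothelial and leukocyte percentiles were 100 and 100 in left forebrain, 99.92 and 99.99 in lung and 99.72 and 99.89 in liver. In small intestine they were 96.44 and 99.67. Window length was not matched in the levels themselves. The median of 12 leukocyte genes was the highest of the 31 lists in 7 organs: left forebrain (3.25), right forebrain (2.74), hindbrain (3.16), lung (2.39), liver (2.02), limb muscle (2.90) and skin (2.48). The pan-endothelial medians there were 1.90, 1.71, 1.81, 1.36, 1.24, 1.39 and 1.30. In small intestine the leukocyte median was 2.03. Heart and kidney had the opposite order, with leukocyte medians of 1.23 and 1.25 beside pan-endothelial medians of 2.44 and 1.88. Over all organs the highest leukocyte genes were Tyrobp, an adaptor of immune receptors (4.45), Spi1, the myeloid transcription factor PU.1 (4.03), and Coro1a (3.60), and the lowest was Ptprc (0.0736). The log2 ratio of the pan-endothelial to the leukocyte median ran from -1.06 in limb muscle to 0.99 in heart. With windows of 2 kb around the denser gene end it became positive in left forebrain (0.03), hindbrain (0.08), lung (0.33) and liver (0.69). It stayed negative in right forebrain (-0.22), small intestine (-0.22), limb muscle (-0.39) and skin (-0.06).

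**Figure D1:**
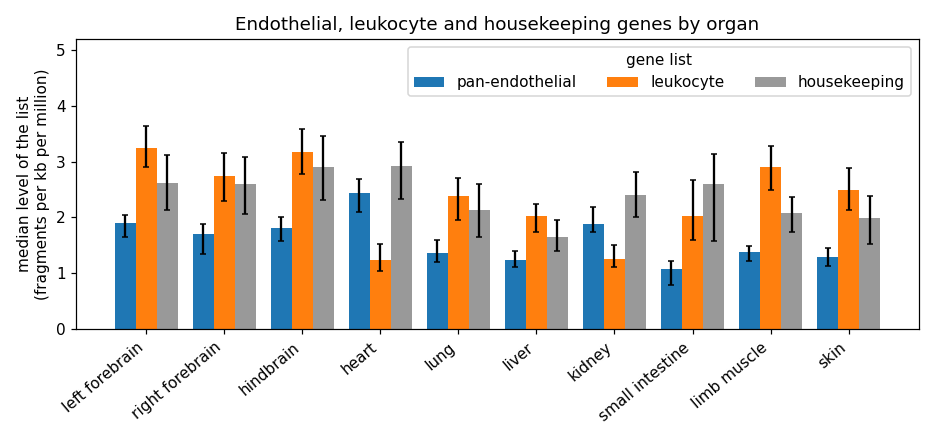
Bars give the median level of pan-endothelial, leukocyte and housekeeping genes in each organ, in fragments per kb per 1000000 fragments, and error bars are 95% intervals for counting error. The leukocyte bar is above the pan-endothelial bar in every organ except heart (1.23 beside 2.44) and kidney (1.25 beside 1.88).

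The brain was compared with the 7 other organs to ask which regulatory genes mark its vessels. Genes of the blood-brain barrier were higher as a group, with a median log2 ratio of 0.53 (0.42 to 0.68), and 7 of 16 members were higher and 0 lower. This median was 0.70 with odd-numbered and 0.35 with even-numbered cells only. Foxf2 (mm10 chromosome 13, 31625816 to 31631406), a transcription factor needed for the barrier, was 3.89-fold higher (3.18 to 4.77), with 221 fragments in 152 brain cells. Foxq1 was 2.74-fold higher (2.00 to 3.74), and Foxl2, which is on neither list, 2.77-fold (2.22 to 3.45). Abcg2, an efflux transporter of the barrier, had a ratio of 0.684 (0.4998 to 0.922). Targets of Wnt/beta-catenin signalling, the pathway that induces the barrier, had a median log2 ratio of 0.49 (0.37 to 0.59), with 2 of 10 members higher. The highest were Apcdd1 (1.74-fold, 1.41 to 2.13), Tnfrsf19 (1.72-fold, 1.44 to 2.03) and Lef1 (1.48-fold, 1.34 to 1.63), and Rnf43 was the lowest (1.12-fold, 0.981 to 1.29). For Lef1 the ratio was 2.51 with windows of 5 kb at the denser gene end. Both lists ranked at percentile 100.

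Some genes of other brain cells were higher in the same libraries. Neurod2 (chromosome 11, 98325415 to 98329645), a neuronal transcription factor, was 2.96-fold higher (2.39 to 3.67). The complement genes C1qb (2.78-fold, 2.23 to 3.47) and C1qc (2.64-fold, 2.22 to 3.14), made by microglia and macrophages, share overlapping windows and count as 1 region. The neural progenitor and glia list had a median log2 ratio of 0.37, with 3 of 12 members higher, the leukocyte list 0.31 with 2 of 12, and the neuron list 0.16 with 3 of 17 higher and 2 lower. In the endothelial-like cells alone, which were grouped partly by such genes, Foxf2 was 14.1-fold higher, Foxq1 7.70-fold, Foxl2 4.71-fold and C1qc 1.72-fold. The lowest genes were Thbs1 (0.288, 0.225 to 0.363) and Hoxb3 (0.345, 0.286 to 0.415). Fibroblast genes had a median log2 ratio of -0.49, and kidney endothelial genes -0.28.

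The 3 brain regions gave like values for the barrier list, with medians of 0.65 in left forebrain, 0.48 in right forebrain and 0.46 in hindbrain. Foxf2 was 3.39-fold higher in left forebrain, 4.29-fold in right forebrain and 4.17-fold in hindbrain. The neuron list differed more, at 0.23, 0.44 and 0.03. Between forebrain and hindbrain, Slc10a2 (10.6-fold, 1.71 to 437), Upf3b (6.74-fold, 1.70 to 58.4), Fam209 (4.70-fold, 1.69 to 18.1) and Gys2 (3.77-fold, 1.61 to 10.8) were higher in forebrain, with between 1 and 6 fragments in hindbrain. Msr1 had 0 fragments in forebrain and 12 in hindbrain, and Itgb8 had a ratio of 0.206 (0.0832 to 0.470). Neural progenitor and glia genes had a median log2 ratio of -0.48 (-0.61 to -0.073) in forebrain against hindbrain, with 2 of 11 members lower and 1 higher. In hindbrain Zic2 was 3.38-fold higher than in the 7 other organs (2.63 to 4.32).

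Left and right forebrain are by label the closest pair in the design, and their libraries also differed. Hox genes of paralog groups 5 to 8 were higher in left forebrain by a median log2 ratio of 0.90 (0.46 to 1.33), with 3 of 11 higher. The liver sinusoid list had a median of 0.27 (0.025 to 0.64), with 2 of 13 higher. The barrier list did not separate the sides (-0.04, -0.18 to 0.21), and neither did the arterial list (-0.03, -0.21 to 0.16). Differences of like size between other organs are therefore also open to differences between libraries. Hoxb6 held 43 fragments in the left and 7 in the right library, a 4.22-fold ratio (1.88 to 11.1). The other genes named by the rule, Apol7a (8.58-fold, 2.14 to 74.8), Hemgn (4.94-fold, 1.93 to 16.1), Bmt2 (4.39-fold, 1.70 to 14.4) and Rps12 (6.87-fold, 1.67 to 60.6), had between 2 and 5 fragments in the right library. Ermard (0.370) and Dact2 (0.269) were the lowest.

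Heart libraries stood out by genes of the endocardium list. Whether endocardial cells carried this signal was not tested. The endocardium list had a median log2 ratio of 1.05 (0.76 to 1.21), with 5 of 8 members higher. Hand2 (chromosome 8, 57320983 to 57324517) was 4.06-fold higher (3.12 to 5.23), Gata6 3.09-fold (2.54 to 3.75) and Npr3, the natriuretic peptide clearance receptor, 2.71-fold (2.14 to 3.40). Nrg1 was the lowest at 1.09-fold (0.877 to 1.34). Kcna5 (4.34-fold, 3.12 to 5.95), Sall1 (3.24-fold, 2.65 to 3.95) and Pdlim1 (2.85-fold, 2.35 to 3.45) completed the highest genes, and Pdlim1 was 4.59-fold with windows of 2 kb. Genes of muscle and heart capillaries, which take up fatty acids, had a median log2 ratio of 0.49 (0.23 to 0.68). Of these, Fabp4 was 1.98-fold higher (1.196 to 3.15) and Fabp5 1.66-fold (1.18 to 2.28), and Aqp7 had a ratio of 1.49 (1.12 to 1.95), under the limit. Lpl had a ratio of 0.573 (0.258 to 1.12). The list did not single out heart, since in kidney its median was 0.51 (-0.020 to 0.65) with 3 of 9 members higher, beside 2 of 9 in heart. This capillary median was -0.035 when cells were thinned to 3000 fragments.

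Pan-endothelial genes were also higher in heart, with a median log2 ratio of 0.55 and 11 of 25 members higher, and in endothelial-like cells alone the median was -0.094. Leukocyte genes were lower, at -0.83 with 9 of 12 members lower, and at -0.37 in endothelial-like cells alone. The lowest genes were the cytokine gene Osm (0.280, 0.183 to 0.410) and Il10ra (0.315, 0.201 to 0.473). Osm had a ratio of 0.717 within the endothelial-like cells, and Il10ra 0.479. Fibroblast genes had a median of 0.45, and cardiomyocyte genes one of -0.40 with 3 of 14 members lower.

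Kidney libraries stood out by Hox genes, which record position along the body axis. Paralog groups 1 to 4 had a median log2 ratio of 0.99 with 9 of 12 members higher, groups 5 to 8 had 0.98 with 10 of 11, and groups 9 to 13 had 0.83 with 11 of 16. The 5 highest genes of the organ were Hoxb7 (chromosome 11, 96285604 to 96290163, 3.72-fold, 3.06 to 4.52), Hoxb8 (3.68-fold), Hoxb9 (3.65-fold), Hoxb5 (3.18-fold) and Hoxb6 (2.996-fold), whose windows overlap. Kidney endothelial genes had a median of 0.25 (0.05 to 0.42), with 3 of 9 higher: Irx3 at 1.93-fold (1.54 to 2.40), Igfbp3 at 1.66-fold (1.21 to 2.24) and Ehd3 at 1.52-fold (1.21 to 1.89). Irx3 was 3.07-fold with windows of 2 kb, and Igfbp5 had a ratio of 0.820 (0.597 to 1.105). Kidney epithelium genes had a median of 0.39 with 2 of 13 higher, and pan-endothelial genes 0.45 with 6 of 25. Leukocyte genes were lower, at -0.90 with 9 of 12 lower, and so were Cd300c2 (0.196, 0.0709 to 0.434) and Osm (0.331, 0.247 to 0.436). In endothelial-like cells alone the pan-endothelial median of kidney was 0.026 and the leukocyte median -0.20. Barrier genes had a median of -0.51 with 5 of 16 lower, against organs that include the brain regions. By level the barrier list stood at 1.49 in left forebrain, 1.73 in right forebrain and 1.59 in hindbrain. Kidney (0.646) lay above heart (0.567) and liver (0.609) and below the other organs, so a low barrier list is not particular to kidney.

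**Figure D2:**
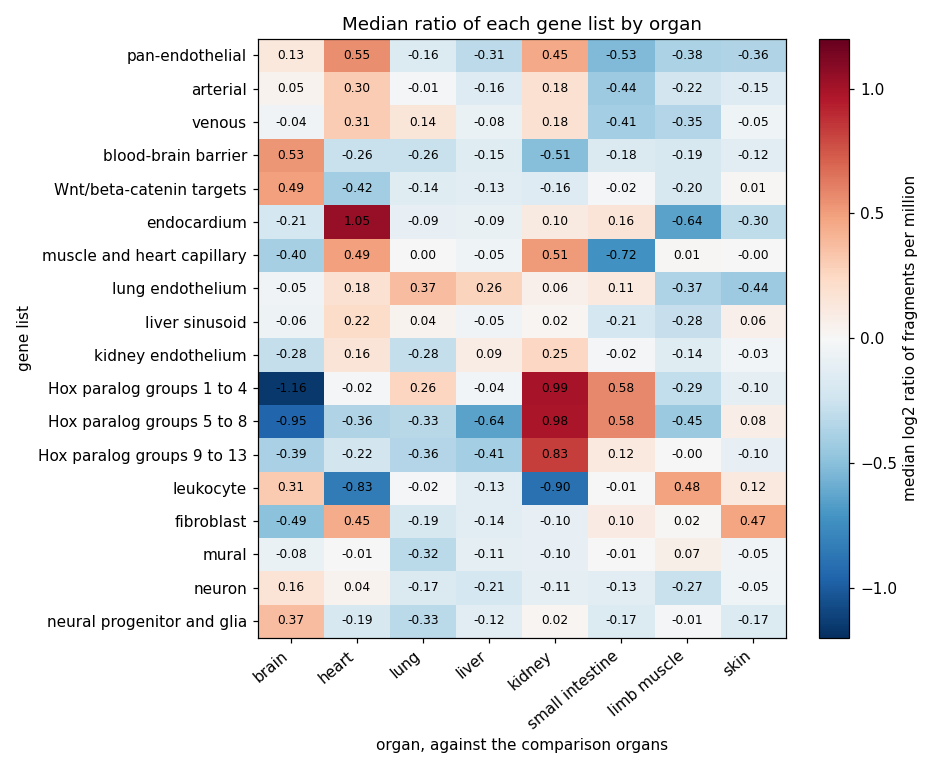
The heat map shows the median log2 ratio of scaled fragment counts for 18 gene lists (vertical) in the brain and 7 other organs (horizontal), each against its comparison organs. The deepest positive fields are endocardium in heart (1.05) and the Hox lists in kidney (0.99, 0.98 and 0.83), and the deepest negative field is Hox groups 1 to 4 in brain (-1.16).

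Lung libraries were marked by the Foxf1 region. Foxf1 (chromosome 8, 121084386 to 121088154), a transcription factor of lung vessels and mesenchyme, was 2.58-fold higher (2.10 to 3.14), although 1 cell gave 15 of its 122 fragments. The neighbouring long non-coding RNA gene Fendrr was 2.16-fold higher (1.82 to 2.55), and the windows of both genes overlap. Within the few endothelial-like cells of lung the ratios were 5.09 and 5.41. Tbx2 had a ratio of 1.47 (1.17 to 1.83), under the limit for higher, and Ednrb had a ratio of 0.624 (0.382 to 0.967). The lung endothelium list had a median log2 ratio of 0.37 (-0.12 to 0.57) with 2 of 11 members higher and 1 lower. It was -0.13 in odd-numbered and 0.62 in even-numbered cells, so the list did not separate lung at this depth. In liver the same list had a median of 0.26 (0.034 to 0.44), with 2 of 11 members higher and 0 lower. Krt80 (2.14-fold), Olfm3 (2.41-fold), F7 (2.16-fold) and Abca8a (2.68-fold) were the other highest genes, and Rnasek (0.240) and Foxc1 (0.244) the lowest. F7 (3.70-fold) and Krt80 (3.07-fold) were also among the leading genes of the leukocyte-like cluster 10, described below. That cluster held 65 lung and 66 liver cells, so these 2 genes cannot be read as marks of lung endothelium. With background taken off, Olfm3 was 15.4-fold and Abca8a 6.76-fold. Their levels in lung were low, at 0.219 and 0.325, beside 0.118 at inactive genes. In the comparison organs both genes lay near background, so subtraction left little there and these ratios are unstable.

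In liver the sinusoid list did not stand out, with a median log2 ratio of -0.05 (-0.16 to 0.19), 1 of 15 members higher and 1 lower. Clec4g, a lectin of sinusoidal endothelium, was 1.504-fold higher (1.03 to 2.16), Maf had a ratio of 1.36 (0.947 to 1.93) and Mrc1 1.26 (0.821 to 1.87). Clec1b had a ratio of 0.365 (0.153 to 0.749). Within the endothelial-like cells, of which liver had few, the median was 0.38. Pan-endothelial genes were lower, at -0.31 with 4 of 25 lower and at -1.10 in endothelial-like cells alone, and Hox groups 5 to 8 at -0.64 with 6 of 11 lower. The highest genes by the rule were Olfr32 (4.71-fold), Serpinb2 (3.90-fold), Sis (3.90-fold), Slco1a1 (3.29-fold) and Gm33084 (3.76-fold), with between 20 and 39 fragments each. Their levels in liver were 0.350, 0.299, 0.116, 0.301 and 0.787 in this order, beside 0.125 at inactive genes. Sis thus lay below the inactive genes, and Olfr32 is itself taken as inactive. Sis was also among the leading genes of cluster 5, a cluster of high background described below. Of the 27 fragments of Sis, 9 came from 1 cell. Liver also had the highest level at inactive genes, 1.45 times that of the other organs (1.41 to 1.49). Arf4 (0.408) and Speg (0.530) were the lowest, and Arf4 was 0.771 with cells thinned to 3000 fragments.

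Limb muscle libraries had higher leukocyte genes, at a median log2 ratio of 0.48 (0.31 to 0.56) with 3 of 12 higher and 0.27 in endothelial-like cells alone, and lower pan-endothelial genes, at -0.38 with 5 of 25 lower. The muscle and heart capillary list had a median of 0.01 (-0.40 to 0.22), and with windows of 2 kb -0.48. Its highest members were Aqp7 (1.55-fold, 1.24 to 1.93), Cd36 (1.27-fold, 0.945 to 1.69) and Pparg (1.08-fold, 0.768 to 1.48), and Tcf15 had a ratio of 0.639 (0.455 to 0.878). Cd36 was 2.29-fold with windows of 5 kb at the denser gene end. The highest genes were Col1a1, which encodes a fibrillar collagen (2.11-fold, 1.82 to 2.44), the cytokine genes Tnfsf14 (2.34-fold, 1.81 to 3.01) and Il4 (2.31-fold, 1.73 to 3.07), Thbs1 (2.04-fold, 1.76 to 2.37) and Pkd1l2 (1.98-fold, 1.80 to 2.18). Pkd1l2 had a ratio of 0.419 with windows of 2 kb, and Col1a1 was 5.14-fold within the endothelial-like cells. Limb muscle had only 39 such cells, and 17 of them were in cluster 8. Col1a1 was a leading gene of that cluster (2.55-fold), in which fibroblast markers were also higher, so the 5.14-fold ratio does not place Col1a1 in muscle endothelium. Apold1 (0.380) and Eef1b2 (0.321) were the lowest.

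Skin libraries had higher fibroblast genes, at a median log2 ratio of 0.47 (0.07 to 0.69) with 3 of 12 higher, and lower pan-endothelial genes, at -0.36 with 8 of 25 lower. The neighbouring Hoxc6 (2.49-fold, 1.90 to 3.22) and Hoxc5 (2.75-fold, 1.87 to 3.93) and the cytokine gene Il13 (2.60-fold, 1.87 to 3.55) were among the highest genes. With cells thinned to 3000 fragments Hoxc6 was 3.80-fold and Il13 5.12-fold. Cacng6 was 3.23-fold higher. Efemp1 was 3.33-fold higher, but 28 of its 42 fragments came from 1 cell. The neighbours Smim27 (0.248) and Topors (0.283) were the lowest. In small intestine, the smallest library, pan-endothelial genes were lower, at -0.53 with 6 of 25 lower. Hox groups 1 to 4 and 5 to 8 each had a median of 0.58, and intestinal epithelium genes had 0.52 (-0.27 to 0.77). Its highest genes were Vtcn1 (2.78-fold), Psmd1 (2.51-fold), Vwa5b1 (2.27-fold), Alpk3 (2.14-fold) and Txndc2 (2.57-fold), with between 24 and 62 fragments each, and Dlc1 (0.367) and Pde7b (0.386) were the lowest.

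Across organs, summed Hox windows had their highest level in kidney in every range, and the brain regions had the lowest in groups 1 to 4. Windows within a Hox cluster overlap, so a fragment can be counted more than once. The intervals of these sums treat such counts as separate and are too narrow. Groups 1 to 4 had levels of 0.982 in left forebrain, 0.744 in right forebrain and 0.840 in hindbrain. Kidney had 2.82 (2.69 to 2.96), small intestine 2.22 (1.95 to 2.52), lung 1.76 (1.62 to 1.91), liver 1.58, heart 1.498, skin 1.44 and limb muscle 1.27. Groups 5 to 8 ran from 0.818 (0.683 to 0.972) in right forebrain to 3.77 (3.57 to 3.99) in kidney, and groups 9 to 13 from 1.08 in hindbrain to 2.68 (2.54 to 2.83) in kidney. In groups 5 to 8 left forebrain (1.42, 1.27 to 1.58) was level with liver (1.43) and limb muscle (1.45) within counting error. By the median over members, small intestine (2.07) stood above kidney (1.99) in groups 1 to 4, and heart (0.877) was lowest in groups 9 to 13. Limb muscle was next in groups 9 to 13, by summed windows, at 1.57 (1.46 to 1.68), beside 1.53 (1.29 to 1.81) in small intestine. In brain the median log2 ratio was -1.16 for groups 1 to 4, -0.95 for 5 to 8 and -0.39 for 9 to 13. The highest gene of each range in kidney was Hoxa2 (6.36), Hoxa7 (6.47) and Hoxa9 (6.68).

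**Figure D3:**
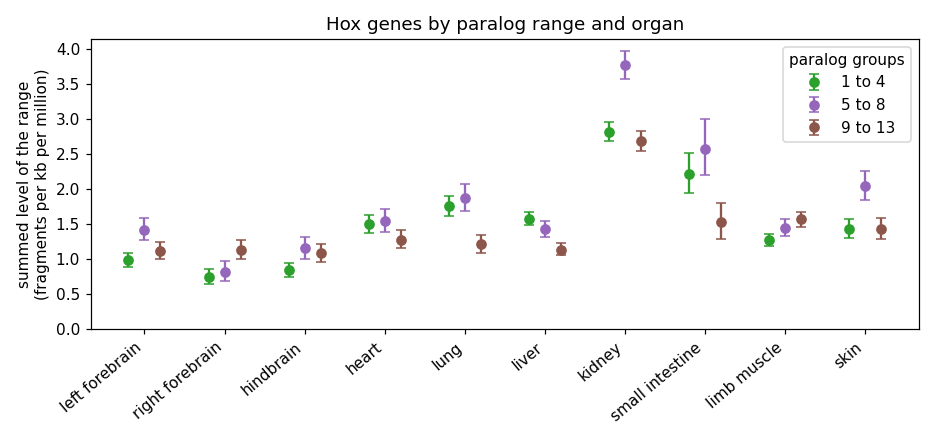
Points give the level of each Hox paralog range by organ, in fragments per kb per 1000000 fragments over the summed windows. The 95% intervals count fragments in overlapping windows as separate and are too narrow. Kidney is highest in every range (2.82, 3.77 and 2.68), and right forebrain is lowest in groups 1 to 4 (0.744) and 5 to 8 (0.818).

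The similarity of organs was measured by correlation across genes, which are not independent replicates. With every organ thinned to the same number of fragments, Pearson's r lay between 0.894 (heart and small intestine) and 0.921 (left forebrain and hindbrain). Left and right forebrain had an r of 0.920. The closest organ to heart was kidney (0.909), and to skin limb muscle (0.916). Whether these pairings are mutual was not settled. In this thinning kidney was slightly closer to left forebrain (0.9100) than to heart (0.9089), and limb muscle to right forebrain (0.91598) than to skin (0.91588). Without thinning both orders turned round. Kidney then had an r of 0.971 with heart and 0.968 with left forebrain, and limb muscle 0.974 with skin and 0.968 with right forebrain. At full depth, heart and kidney had a Pearson r of 0.971 and a Spearman rho of 0.972 across genes, and 0.790 in bins of 5 kb.

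Single cells were compared to ask how far they separate by organ. On average over organs 34.4% of a cell's nearest neighbours came from its own organ, where organ sizes give 9.97% and fragments dealt at random gave 10.4%. The share was 57.7% in heart, 50.1% in kidney, 40.6% in limb muscle, 40.6% in liver, 33.5% in right forebrain, 33.5% in hindbrain, 30.3% in left forebrain, 29.5% in lung, 22.3% in skin and 5.68% in small intestine. Cells of the 3 brain regions mixed with each other: between 79.2% and 88.7% of their neighbours came from the brain, where 30.8% was expected. Lung cells had 34.0% of their neighbours in liver, and skin cells 40.8% in limb muscle. With cells thinned to 3000 fragments, which left 1477 cells, the mean share was 21.1%.

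**Figure D4:**
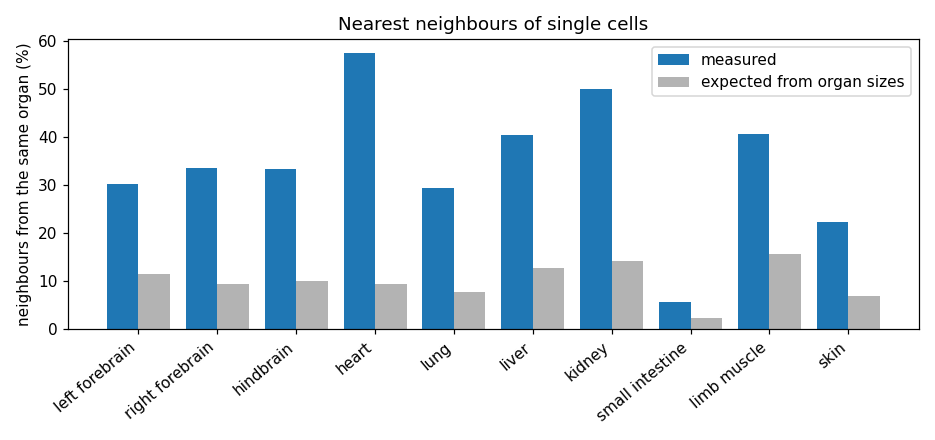
Bars give the percentage of a cell's nearest neighbours from its own organ, beside the percentage expected from organ sizes. The measured share is above the expected one in every organ, from 5.68% beside 2.39% in small intestine to 57.7% beside 9.39% in heart.

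The cells formed 13 clusters. Clusters 1 (372 cells), 6 (266) and 8 (179) were named endothelial-like from the fixed markers, with pan-endothelial, barrier and endocardial genes leading in turn, and in cluster 8 the pan-endothelial genes alone had a level of 1.40, beside 2.67 in cluster 1 and 1.79 and 1.55 in the unnamed clusters 12 and 13, and 4 of 12 fibroblast markers were higher. Clusters 2 (370), 7 (259), 9 (159) and 10 (149) were named leukocyte-like, and immune genes such as C1qc, Nlrp3, Camp and Trem3 led them in turn. The other 6 clusters stayed unnamed: cluster 3 held markers of both neurons and neural progenitors, cluster 4 deep cells (median 7341 fragments), cluster 5 high background, cluster 11 genes such as Il4 and Tpsb2, cluster 12 Foxf1, and cluster 13 had no leading list.

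With bins at listed genes left out of the clustering, 25.7% of all cells (24.2 to 27.3) were in endothelial-like and 25.6% (24.1 to 27.2) in leukocyte-like clusters. The endothelial-like share was 72.2% in heart, 52.2% in kidney, 33.1% in hindbrain, 29.1% in left forebrain, 20.6% in right forebrain, 9.46% in small intestine, 8.54% in limb muscle, 5.96% in lung, 5.14% in liver and 4.19% in skin. Of the 208 such cells in heart, 93 were in a cluster led by the endocardium and fibroblast lists, with as many markers of other classes as of its own among its top genes. The cluster led by pan-endothelial genes held 39.2% of heart and 44.6% of kidney cells. The leukocyte-like share was 44.4% in limb muscle, 34.1% in hindbrain, 32.8% in left forebrain, 31.2% in skin, 31.1% in lung, 25.7% in small intestine, 24.0% in right forebrain, 22.6% in liver, 5.77% in kidney and 3.82% in heart. Different clusters held the endothelial-like class: in the main clustering cluster 6 took 97.4% of its cells from the brain, while cluster 1 held 46.4% of kidney and 39.2% of heart cells and cluster 8 held 33.3% of heart cells. With 1 library per organ, a cluster of 1 organ cannot be separated from its library. At resolution 0.5 the endothelial-like share was 0.694% in heart and 0.231% in kidney. Thinning to 3000 fragments gave leukocyte-like shares of 8.26% in lung and 8.76% in liver.

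The naming rule, written after clusters had been seen, left 7 clusters of this second clustering unnamed. A cluster with Foxf1 and Aplnr, a receptor gene of endothelial cells, among its leading genes had a pan-endothelial median log2 ratio of 0.36 with 5 of 25 members higher, short of the limit of 0.5. Its highest list was the keratinocyte list, at 0.53 with 1 of 11 members higher. This Foxf1 cluster held 20.8% of liver (16.9 to 25.2) and 18.3% of lung cells (13.6 to 23.8), more than the endothelial-like shares of these organs, beside 5.31% of kidney, 1.04% of heart, 1.04% of limb muscle and 0.930% of skin cells. A cluster with neuron and neural progenitor markers held 27.4% of left forebrain, 46.3% of right forebrain, 16.7% of hindbrain, 9.46% of small intestine, 7.44% of skin, 4.79% of limb muscle, 3.002% of kidney, 1.39% of heart, 0.851% of lung and 0.257% of liver cells. A cluster with some fibroblast markers and high background held 19.3% of liver, 17.0% of lung, 12.7% of kidney, 12.2% of small intestine, 11.5% of heart, 9.77% of skin, 4.59% of hindbrain, 4.58% of limb muscle, 2.44% of right forebrain and 1.42% of left forebrain cells. A cluster led by the neutrophil genes Camp and Ngp, with a leukocyte median log2 ratio of 0.49 under the limit of 0.5, held 19.5% of liver, 14.5% of lung, 6.67% of limb muscle, 1.40% of skin, 1.31% of hindbrain, 0.855% of left forebrain, 0.693% of kidney and 0.347% of heart cells. It held 0 of 287 right forebrain cells and 0 of 74 small intestine cells, which allows up to 1.28% and 4.86% (exact upper bounds). The main clustering, which named its Camp cluster leukocyte-like, gave leukocyte-like shares of 44.7% in lung (38.2 to 51.3) and 40.4% in liver (35.4 to 45.4). The 3 other unnamed clusters held deep cells, cells with Il4 and Tpsb2 among the leading genes (26.05% of skin, 15.6% of limb muscle and 13.5% of small intestine cells), and cells without a leading list.

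Distal bins named by the rule in brain, heart, lung, liver and kidney were piles with most or all fragments from 1 cell. Those in small intestine, limb muscle and skin had at most 4 fragments from 1 cell. The first liver bin (chromosome 4, 37032001 to 37033000) held 21 fragments, all from 1 cell. Counting each cell once per bin, chosen after these piles were seen, gave other regions. In lung a bin on chromosome 8 (121047001 to 121048000), 6882 bp from Fendrr, was 9.57-fold higher (3.88 to 23.2) with 11 fragments. In limb muscle a bin within Jdp2 (chromosome 12, 85618001 to 85619000) ranked by both counts, at 10.6-fold (4.48 to 27.03) with all fragments and 8.04-fold (3.18 to 21.3) with each cell once. In heart a bin on chromosome 14 (86510001 to 86511000) was 12.6-fold higher (4.74 to 34.4), and in brain a bin on chromosome 19 (42461001 to 42462000) 17.1-fold (3.74 to 159).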

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

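The tests below were set before their values were seen, except the test of pairs linking 2 organs and the count of groups with a second class, which were chosen only after the result was seen.

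Fragments not analysed as sets of their own were 3252 mitochondrial fragments, 7425 fragments on unplaced sequences and 1479 fragments on the Y chromosome, summed over all cells. Each is above the 3 fragments that a count of 0 allows, which says only that such fragments were present. None of these 3 sets was compared between organs as a set. The Y chromosome fragments did enter the organ totals, and any within windows of annotated genes there entered the gene ratios.

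Leukocyte genes were among the highest lists in cells labelled endothelial. With cells grouped on odd-numbered chromosomes alone, leukocyte genes on even-numbered chromosomes were 2.652 times as high (2.47 to 2.85) in leukocyte-like as in endothelial-like cells, which argues against fragments spread evenly over all cells. Pan-endothelial genes on even-numbered chromosomes had a ratio of 0.429 (0.411 to 0.449) in the same cells, which argues against leukocyte genes marked within endothelial cells as the whole source. Of the 4 groups past the leukocyte limits, 0 were left out for a second class. The endothelial-like cells still held the leukocyte genes at a level of 2.00, beside 2.54 for pan-endothelial genes, and 1 group of 92 of them had median log2 ratios of 0.65 (leukocyte) and 0.53 (pan-endothelial), so some leukocyte signal in endothelial cells stays open. Cells of another type among those profiled remain a candidate explanation, led by Tyrobp, Spi1 and Coro1a, and no gene of the leukocyte list is in another list. Any sort that would remove such cells is not given in the sources used here, and differences between organs in their resident immune cells stay open as untested.

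Inactive genes were higher in the liver and lung cells. Fragments in bins over 100 kb from any gene were 1.49 times as frequent in liver as in the other organs (1.48 to 1.503) and 1.27 times in lung, so more unspecific fragments in these cells may account for it. A few deep cells are argued against, since with every cell at equal weight the liver ratio at these genes was 1.495. The organ itself, as a biological difference, was not tested.

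Identical fragments in more than 1 cell made up 2.56% of all fragments (365758). Pairs of cells shared the same start and end 20.6 times as often as the same start with ends 20 to 29 bp apart, which argues against coincidence of insertion sites. The share of identical pairs that link 2 organs was 0.435, or 43.5%, where random pairs of fragments give 88.1%, which argues against crossing between cells whatever their organ. Crossing between cells handled together stays open, and no biological explanation was tested.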

How the results depend on the processing

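The windows at gene ends, the settings on background, cell classes, listed genes, seeds and SVD were chosen after the data were seen. No paired analysis was possible because cell numbers only name cells and each organ is 1 sample without a test. The planned start site windows, gene body with upstream flank, scaling to start sites and motif search were not run; ratios with under 10 fragments observed and expected, and the pan-endothelial to leukocyte ratio in cells chosen by those genes, gave no value.

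In endothelial-like cells alone the median log2 ratio was 1.35 for the barrier list and 1.0996 for Wnt targets in brain. It was 0.72 for endocardium in heart and 0.38 for the liver sinusoid list. That of pan-endothelial genes in heart reversed to -0.094. The barrier, endocardium, sinusoid and pan-endothelial lists were among those that named these cells, so their values here are partly fixed by the choice of cells. Without leukocyte-like cells Wnt targets were at 0.59. Thinned to 3000 fragments, the barrier list was at 0.37 and the muscle and heart capillary list in heart reversed to -0.035. Odd-numbered cells gave 0.70 (barrier), 0.72 (endocardium) and -0.13 (lung list); even-numbered cells gave 0.35 (barrier) and 0.62 (lung list). Windows of 5 kb at the denser gene end gave 0.78 (barrier) and 1.30 (endocardium), and those of 2 kb gave 0.40 (barrier), 1.42 (endocardium) and -0.48 (muscle and heart capillary, limb muscle). With these 2 kb windows the log2 of pan-endothelial over leukocyte level reversed in left forebrain (0.029), hindbrain (0.078), lung (0.33) and liver (0.69), and Pkd1l2 in limb muscle to 0.419. Taking off background gave 1.77 for endocardium. The kidney endothelium list stayed between 0.16 and 0.38.

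The mean share of neighbours from the same organ was 28.4% with gene windows only, 21.1% thinned, 29.8% on odd-numbered chromosomes and 27.4% with approximate SVD. The endothelial-like share of all cells was 21.5% thinned, 8.70% at resolution 0.5, 24.8% at resolution 2, 23.3% with approximate SVD and 20.9% with 1 other seed. The leukocyte-like share was 19.4%, 35.2% and 28.2% under the first 3 of these, and 25.6% without bins of listed genes, whether or not the leading-gene condition was applied. A neuron-like class appeared with approximate SVD (16.7% of cells) and at resolution 2 (2.45%). The adjusted Rand index with the main clusters was at least 0.896 for 5 other seeds, 0.794 without listed genes and 0.424 with approximate SVD. Of 2603 values of 239 other results, 2080 stayed within their interval or limit, 517 moved beyond it and 6 reversed, printed above. The cause was not tested, except that thinning leaves out shallow cells. Small intestine had the fewest fragments (383386), and 37.5% of its simulated 1.5-fold genes were recovered, beside 42.5% in lung and 45% in brain. Genes set at the limit of the rule itself were often missed in every organ, so these values do not rank organs by depth.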

Other observations

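No test in this part was chosen after a result was seen, and the values below come from lists fixed before the data were examined.

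Lists of vessel types also had different medians between organs. Arterial genes had median log2 ratios of 0.30 in heart and 0.18 in kidney and of -0.44 in small intestine and -0.22 in limb muscle. Pan-endothelial genes moved the same way and further, at 0.55, 0.45, -0.53 and -0.38, so these values do not show a change of vessel type apart from that list. Over all organs the Notch ligand genes Jag2 (5.29) and Dll4 (5.07) and the receptor gene Notch4 (4.21) had the highest levels of that list, and Bmx (0.167) the lowest. Venous genes had medians of 0.31 (0.049 to 0.51) in heart, 0.18 (-0.077 to 0.57) in kidney, 0.14 (-0.067 to 0.28) in lung, -0.35 (-0.63 to -0.20) in limb muscle and -0.41 (-0.65 to 0.049) in small intestine, and were led over all organs by Icam1 (4.94), Plvap (2.82) and Ephb4 (2.52). Tip cell and angiogenic genes were at 0.31 in heart and 0.24 in kidney, below the pan-endothelial values there (0.55 and 0.45), and were led by Pdgfb (4.52). Lymphatic genes had a median of -0.31 (-0.45 to -0.11) in brain, with 0 of 7 higher and 1 lower. They did not separate kidney (-0.37, -0.55 to 0.14), with 2 higher and 1 lower. No fragment lay at Ccl21a in any organ. The deposited reads had mapping quality scores of 31 or more. This 0 therefore cannot tell an unmarked gene from one whose reads did not reach such scores.

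Mural genes had a median of -0.32 in lung and between -0.11 and 0.07 in brain and the other organs. Erythroid genes had a median of -0.49 (-0.90 to -0.18) in heart and 0.21 (-0.073 to 0.37) in brain. Endocardial genes had a median of -0.64 in limb muscle with 4 of 8 members lower, against organs that include heart. By level, hindbrain (0.651) and right forebrain (0.774) lay below limb muscle (0.788) for this list. Hepatocyte genes had a median of -0.05 in liver, and Alb had a level of 0.0572 over all organs. Skeletal muscle genes had a median of 0.08 in limb muscle, keratinocyte genes 0.12 in skin and lung epithelium genes -0.04 in lung, each with 0 members higher or lower. Cell cycle genes had medians between -0.31 (skin) and 0.19 (heart), and endothelial-to-mesenchymal transition genes between -0.20 (small intestine) and 0.25 (heart).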
